A study of Mus musculus with 6 samples.

How the data were processed

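Endothelial cells were sorted by flow cytometry from subcutaneous B16F0 melanoma tumours of C57BL/6 mice. B16F0 is a transplantable mouse melanoma line. Tumours grew for 17 days, and mice received the antibody 15C4 or control IgG at 50 mg/kg every 3 days. The series holds 3 libraries from 15C4-treated and 3 from IgG-treated tumours, made from PCR-amplified cDNA with the Nextera XT kit, per the labels' protocols. The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may in part be technical.

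The authors deposited a whole-number count per gene symbol for each library, 24421 symbols in all. Per the submitters' processing notes, fastp, STAR 2.5b, featureCounts and DESeq2 were used, and the builds mm10 and mm9 are named without roles. Which build the counts rest on, the annotation and the strand setting are not given in the sources used here. The authors also deposited a table for the whole series. Its raw counts equalled those of the single libraries for the 24394 symbols spelled alike, and 27 symbols in it were written as dates. Per the file headers, it also holds normalised values, which are a score here because the authors divided counts by a size factor per library and rounded them. Per the file headers it gives a log2 fold change, which is IgG over 15C4 by its sign against the group means. It also holds the authors' p-value and adjusted p-value per gene, used here only where named as deposited.

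The counts were tested here with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) after TMM normalisation. Genes were kept by filterByExpr, which asks for a minimum count of 10 scaled to library size and a total of 15. Treatment was the only term, and fold changes are 15C4 over IgG. Adjusted p is by Benjamini-Hochberg with a threshold of 0.05. Sums over lists, and the single genes given beside them to describe the cell types in each library (Tyrp1, Cdh5, Mmrn1, Lyve1, Gzma, Nkg7, Ccl5, Ptprc, Tyrobp, Fcer1g, Ccr2, Csf1r, C1qc, Mrc1 and Lum), are CPM of all counts, without TMM factors. Gene values given as a mean with SD are CPM further scaled by the TMM factors. Means are given with the standard deviation (SD) of 3 libraries. The SE of a log2 fold change was derived from the test, as its absolute value over the square root of the quasi-likelihood F statistic. For 3 libraries against 3, the smallest p an exact permutation test can give is 0.1.

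Before the data were examined, 43 gene lists were fixed. They cover endothelial states, cell processes, RNA quality and the other cell types a tumour sort could hold. The 33 lists with at least 3 tested genes were compared by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Camera sets a list against all other tested genes, whose mean difference was -0.37 on the log2 scale (median -0.16). Camera with an estimated correlation and fry were run beside it. The 13 mitochondrially encoded genes have no symbol in the counts, so that list could not be measured.

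The rule for named genes was also fixed beforehand. Where no gene passed, it takes the 10 genes per direction with the smallest unadjusted p, given as values that did not pass, with predicted genes left out while others remained. It adds Lrg1, the members of each list with the smallest p and the most abundant markers of other cell types. A fold against a group with 0 counts is a lower bound at 3 counts over the group. With 1 to 3 counts, a ratio with its 95% counting interval is given. Intervals and bounds cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Coordinates are from GENCODE M21 on GRCm38, which held 23376 of the 24421 symbols.

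Total counts ranged from 5175600 to 19572202 per library. The tests were checked on simulated counts with the means, library sizes and fitted dispersion of this comparison, with 200 changed genes and 10670 genes tested. edgeR recovered 8 of 50 genes changed 4-fold, 29 of 50 changed 16-fold, 37 of 50 changed 64-fold and 39 of 50 changed 256-fold, with 4 false calls. DESeq2 1.42.0 recovered 19, 39, 41 and 38 of 50 at these sizes with 76 false calls, and limma-voom 10, 18, 28 and 26 of 50 with 6. In a separate simulation of 10658 genes, camera recovered 3 of 3 lists shifted 4-fold and called 0 of 28 others. The simulated genes were drawn independently of each other. This check therefore cannot show how often camera with the preset correlation calls lists wrongly where genes are correlated. The gene check planted 200 changed genes of up to 256-fold. An adjusted p is harder to pass where fewer genes change, so this recovery may overstate the power behind the gene counts here. The 4-fold list shift exceeded the median shift of every list that passed in the real counts, so recovery of smaller shifts was not checked.

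Alternatives planned beforehand were other normalisations, filters, tools, thresholds and set tests, the replicate number as a block, and each library left out in turn. A covariate for endothelial content, the fit without 15C4 3 and IgG 3, an estimated correlation combined with the covariate, the stricter filter, the block or left-out libraries, and DESeq2 without a prior filter, with and without its outlier cutoff, were added after seeing the data. The covariate was the mean log2 CPM of the pan-endothelial list in each library. No library was left out of the main analysis, and no pair of libraries held identical counts.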

Results

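Gene expression was measured by RNA sequencing in endothelial cells sorted from B16F0 melanoma tumours of mice treated with 15C4, a function-blocking antibody against the secreted glycoprotein LRG1, or with control IgG. The comparison asks how the antibody alters the expression profile of tumour endothelium. The 15C4 libraries held 8400846, 19572202 and 6392700 counts (15C4 1, 2 and 3) and the IgG libraries 5175600, 9641617 and 11669085 (IgG 1, 2 and 3). Between 10413 and 13707 genes were detected per library. 15C4 3 stood apart on the first principal component, which held 45.7% of the variance, and had 1537 of the 11144 tested genes at 0, against 31 to 507 in the others.

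Transcripts of the melanocyte lineage were abundant in every library. In CPM of all counts, without TMM factors, the 13 genes of this list summed to 27183 ± 2215 CPM in 15C4 and 27078 ± 2623 CPM in IgG (SD, n = 3 each; two-sided exact permutation p = 1), led by Dct and Tyrp1, enzymes of melanin synthesis. Tyrp1 (GRCm38 chromosome 4, 80834123 to 80851719) alone lay between 6369 and 8675 CPM. The 22 pan-endothelial genes summed to 1664, 3532 and 1666 CPM in the 15C4 libraries and to 2072, 2930 and 258 CPM in the IgG libraries. Melanocyte transcripts thus exceeded pan-endothelial ones 93.8-fold in IgG 3 and between 6.97-fold and 17.1-fold in the others. Changes in genes of general processes, such as interferon response, cholesterol synthesis or hypoxia, can therefore not be assigned to endothelial or tumour cells. Cdh5, which encodes VE-cadherin (chromosome 8, 104101625 to 104144511), was at 46.3 CPM in IgG 3 and between 505 and 1240 CPM elsewhere.

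Markers of other cell types, also in CPM of all counts, differed between the libraries. Markers of lymphatic endothelium summed to 1168 CPM in IgG 2 and to between 11.6 and 63.8 CPM in the others. Mmrn1 was at 578 CPM and Lyve1, a hyaluronan receptor of lymphatic vessels, at 367 CPM in IgG 2, while Lyve1 had 15 counts in IgG 1 and 0 in the remaining libraries. T and NK cell markers summed to 693 CPM in IgG 1, with Gzma at 178 CPM and Nkg7 at 105 CPM, and to 223 CPM in 15C4 1, where Ccl5 made up 214 CPM. Macrophage and monocyte markers summed to 212 CPM in IgG 1 and to at most 78.0 CPM elsewhere. In IgG 1, Ptprc made up 86.9 CPM, Tyrobp and Fcer1g 42.9 CPM each and Ccr2 15.5 CPM. Csf1r was at 0.386 CPM and C1qc and Mrc1 at 0.193 CPM there, while 15C4 2 held C1qc at 19.7 CPM and Mrc1 at 13.5 CPM. The macrophage and monocyte sum in IgG 1 therefore does not by itself show macrophages in that library. Fibroblast markers reached 156 CPM in 15C4 3, of which Lum made up 151 CPM, and 125 CPM in IgG 1. Pericyte and smooth muscle markers summed to between 10.5 and 103 CPM. Dendritic, B cell, neutrophil, erythroid, platelet, keratinocyte and skeletal muscle markers stayed at or below 10.2 CPM in every library, and adipocyte markers had 0 counts.

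**Figure D1:**
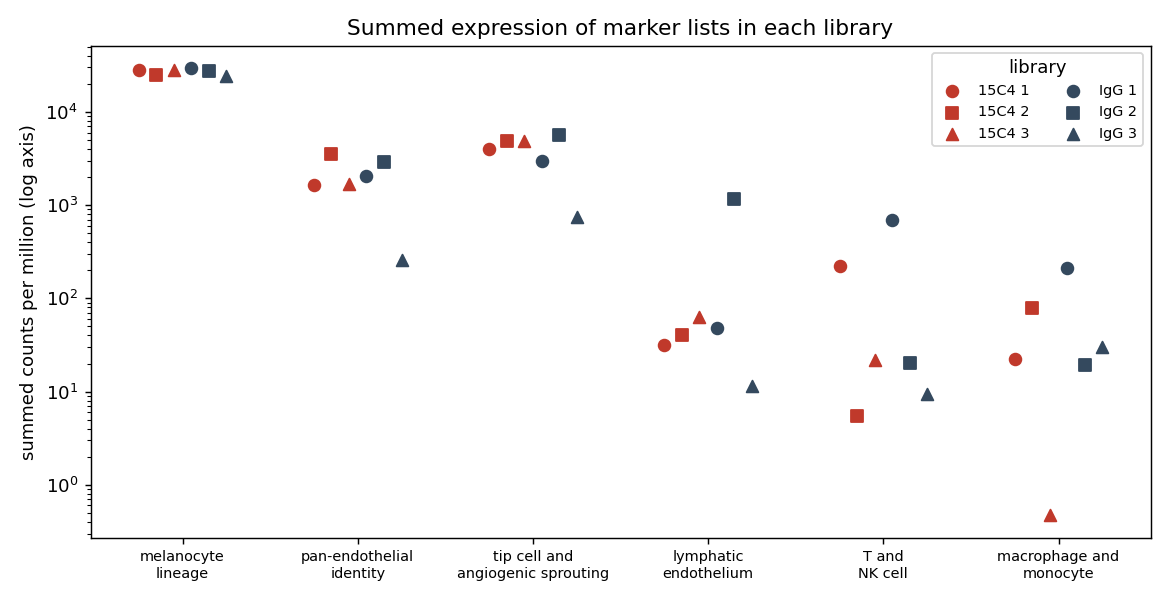
Summed CPM of 6 marker lists on a log axis, 1 point per library (red, 15C4; blue, IgG). Melanocyte transcripts lie between 24213 and 29360 CPM in all libraries, while the pan-endothelial sum of IgG 3 is 258 CPM.

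No single gene passed the test between 15C4 and IgG. Among the genes with the smallest unadjusted p, Ifih1, a cytosolic sensor of viral RNA, was at 184 ± 35.9 CPM in 15C4 and 58.2 ± 4.31 CPM in IgG (log2 fold change 1.66, SE 0.36). Id2, a transcriptional regulator induced by BMP signalling, was at 488 ± 28.04 against 166 ± 72.5 CPM (1.56, SE 0.40), and Kcne3, a potassium channel subunit of tip cells, at 345 ± 65.6 against 109 ± 52.9 CPM (1.66, SE 0.45). Aurkb, a mitotic kinase, was at 0.457 ± 0.357 CPM in 15C4 and 25.7 ± 13.8 CPM in IgG (-5.71, SE 1.15), and the transcription factor gene Foxp2 at 1.12 ± 1.07 against 63.7 ± 12.6 CPM (-5.78, SE 1.17; SD, n = 3 in each case). The log2 fold change was -6.51 for Aurkb without 15C4 2 and -6.50 for Foxp2 without 15C4 1.

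The count was 0 of 11144 genes with edgeR, with a smallest adjusted p of 0.689. At an unadjusted p under 0.05 there were 288 genes, 140 higher and 148 lower, where 557 would be expected by chance. limma-voom called 0 genes, with or without sample weights, and 461 and 508 at the unadjusted threshold. DESeq2 called 26 genes, 3 higher and 23 lower, with 455 at the unadjusted threshold. Its calls included Ifih1 (adjusted p = 0.0112), Hmcn1 (0.0385) and Zfp780b (0.0274), which were higher in 15C4, and Foxp2 (4.33e-07) and Aurkb (7.89e-05), which were lower. Of its 26 calls, 17 had 0 counts in at least 2 of the 6 libraries. The 15C4 and IgG libraries did not overlap for 9.50% of tested genes, where chance gives 10%. The fitted biological coefficient of variation was 0.861.

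The other genes with the smallest unadjusted p that were higher in 15C4 were Hmcn1 (log2 fold change 2.46, SE 0.61), Zfp91 (1.64, SE 0.41), Frk (2.05, SE 0.52), Zfp780b (2.96, SE 0.76), Aph1c (1.71, SE 0.46), Orc5 (2.05, SE 0.60) and the noncoding Platr22, which had 229 counts in 15C4 and 1 in IgG, a ratio of 188 (95% counting interval 33.3 to 7441). Without 15C4 3 the log2 fold change was 1.66 for Hmcn1 and 1.29 for Orc5. The 1 count of Platr22 was in IgG 1, without which it was at least 50.4-fold higher, and the ratio was 118 without IgG 2 and 106 without IgG 3. On the lower side, Rab39b (chromosome X, 75572046 to 75578231) had 0 counts in the 15C4 libraries and 779 in IgG, at least 317-fold lower. Kcnn4, a calcium-activated potassium channel, was at least 332-fold lower, Tinf2 at least 108-fold, Zfp763 at least 116-fold and Hexim2 at least 109-fold. IgG 3 held 662 of the 815 IgG counts of Kcnn4 and 177 of the 269 of Hexim2, and without it the bounds were 110-fold and 66.3-fold. Without 15C4 2, the deepest library, they were 139-fold for Rab39b, 146-fold for Kcnn4, 47.4-fold for Tinf2, 51.2-fold for Zfp763 and 48.2-fold for Hexim2. Gnai1 had 2 counts in 15C4 and 577 in IgG, a ratio of 352 (95% counting interval 97.1 to 2915), and Hist2h2be 1 and 344, a ratio of 420 (74.9 to 16635). The ratio of Hist2h2be was 185 without 15C4 2, 241 without IgG 2 and 648 without IgG 3, and without 15C4 1, which held the 1 count, it was at least 102-fold lower. Zfp959 was at 0.145 ± 0.164 CPM in 15C4 and 19.5 ± 3.01 CPM in IgG (SD, n = 3 each), with a log2 fold change of -6.79, or -7.94 without 15C4 2. Lrg1, which encodes the antibody's target (chromosome 17, 56119678 to 56122001), had 0, 65 and 0 counts in the 15C4 libraries and 4, 190 and 0 in the IgG libraries and was too low to be tested.

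**Figure D2:**
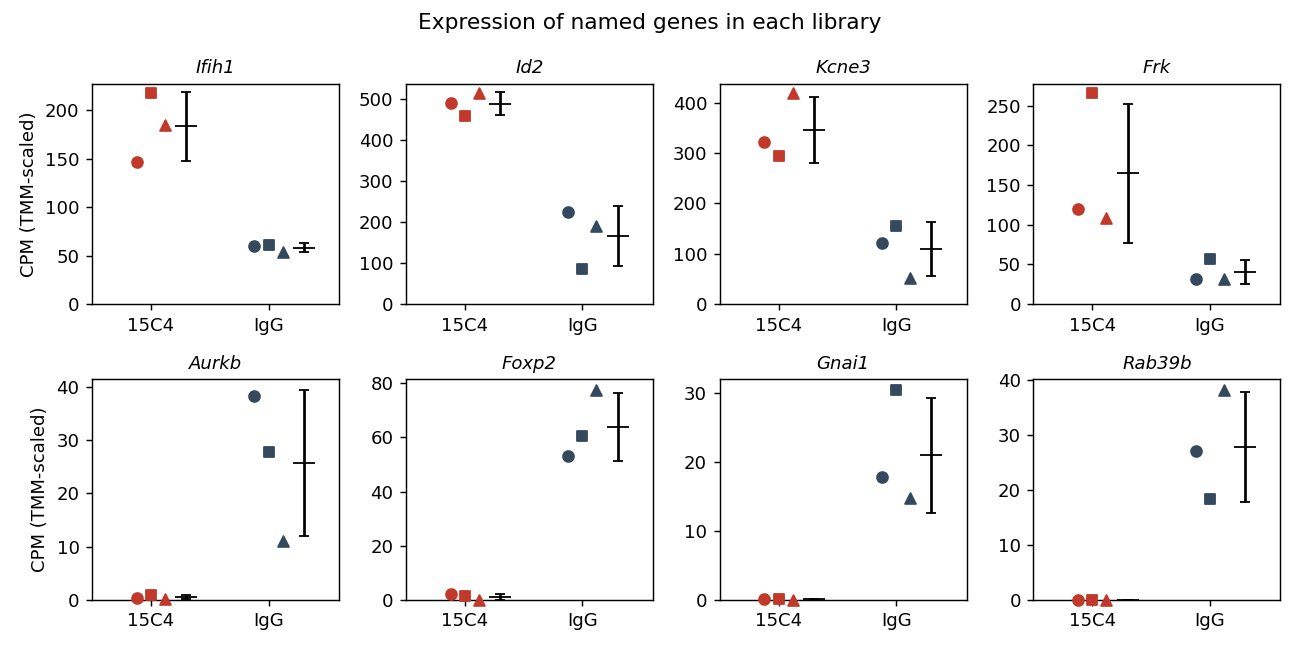
TMM-scaled CPM of 8 named genes, 1 point per library, with the mean and SD of 3 libraries beside them. The groups do not overlap for any of the 8, which were chosen for a small p in these same counts. Ifih1 was at 184 CPM in 15C4 and 58.2 CPM in IgG on average, and none of the 8 passed the edgeR test over all genes.

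Of 33 gene lists tested, 8 passed the camera test with a preset correlation, 7 higher and 1 lower in 15C4. None passed with an estimated correlation (smallest adjusted p = 0.757 with an estimated correlation, the value of each of the 8). None passed by fry for a shared direction (smallest adjusted p = 0.847). List medians are of log2 CPM, as camera uses, and members are counted by the edgeR fits, whose medians were 0.53 for tip cell, 0.36 for pan-endothelial, 0.93 for arterial, 0.71 for Notch, 0.46 for interferon, 0.51 for cholesterol, 0.49 for unfolded protein response and -0.62 for hypoxia genes. Tip cell and sprouting genes rose, with 20 of 21 fitted above 0 and a median log2 difference of 1.09 (adjusted p = 0.000161). Beside Kcne3, Adm, which encodes adrenomedullin, was at 137 ± 124 against 35.6 ± 37.2 CPM, Inhbb at 255.5 ± 141 against 108 ± 90.8 CPM, and Angpt2, a ligand of the TIE2 receptor, at 514 ± 243 against 280 ± 173 CPM. Pan-endothelial genes (18 of 22 above 0, median 0.83, adjusted p = 0.00382), arterial genes (8 of 9, median 0.98, adjusted p = 0.00382) and Notch signalling genes (9 of 11, median 0.71, adjusted p = 0.0184) also rose. Hey1, a Notch target, was at 68.0 ± 18.1 against 18.0 ± 9.88 CPM, and Jag1, a Notch ligand, at 74.7 ± 3.78 against 39.2 ± 14.2 CPM. Both are on the arterial and Notch lists, and Sox17 is on the arterial and pan-endothelial lists, so these calls are not independent. Of the pan-endothelial members, Esam was at 89.3 ± 39.8 against 44.1 ± 34.3 CPM and Sox17 at 18.2 ± 12.1 against 8.001 ± 6.13 CPM. The summed CPM of these lists overlapped between the groups (two-sided exact permutation p = 0.4 for tip cell, 0.8 for pan-endothelial, 0.8 for arterial and 0.7 for Notch signalling genes, where 0.1 is the smallest possible). IgG 3, with its pan-endothelial sum of 258 CPM, was in the IgG group of each comparison. Without it these calls were lost: tip cell median 0.12 (adjusted p = 0.150), pan-endothelial -0.29 (0.814), arterial 0.36 (0.122) and Notch -0.05 (0.376). Without 15C4 2, the pan-endothelial (median 0.28, adjusted p = 0.304), arterial (0.95, 0.124) and Notch lists (0.21, 0.567) lost theirs, and Notch also without 15C4 1 (0.68, 0.0526). Medians were larger without IgG 2 for the tip cell (1.77) and pan-endothelial lists (1.44) and without 15C4 3 for Notch (1.21).

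Interferon response genes rose, with 25 of 30 fitted above 0 and a median log2 difference of 0.53 (camera adjusted p = 0.000247; adjusted p = 0.757 with an estimated correlation). Igtp, an interferon-induced GTPase, was at 571 ± 13.7 CPM in 15C4 and 254 ± 167 CPM in IgG, and Rtp4 at 371 ± 125 against 218 ± 62.8 CPM. The summed CPM of the list was 7628 ± 2753 against 6188 ± 3848 (SD, n = 3 each; two-sided exact permutation p = 0.7). The call held with each library left out in turn, but the median was 0.93 without IgG 2, whose summed interferon response CPM of 10622 was above the other 5. Cholesterol synthesis genes rose (15 of 18 above 0, median 0.37, adjusted p = 0.00382; 0.757 with an estimated correlation). Their summed CPM was 2376 ± 589 against 1557 ± 323, with a two-sided exact permutation p of 0.1, the smallest possible. Idi1, an isomerase of the pathway, was at 62.0 ± 43.3 against 15.5 ± 8.11 CPM, and Sc5d at 179 ± 80.8 against 79.1 ± 8.89 CPM. This call was lost without 15C4 2 (median 0.22, adjusted p = 0.208), and the median was 0.67 without 15C4 1, 0.57 without 15C4 3 and 0.66 without IgG 3. Unfolded protein response genes rose (13 of 15 above 0, median 0.29, adjusted p = 0.0184; 0.757 with an estimated correlation), with Herpud1 at 133 ± 0.700 against 51.9 ± 29.0 CPM and Dnajb9 at 94.2 ± 66.1 against 39.7 ± 15.4 CPM. The exact permutation p of their summed CPM was 0.3. Their call was lost without 15C4 2 (median 0.40, adjusted p = 0.124), 15C4 3 (0.11, 0.227) or IgG 3 (0.23, 0.0903), and the median was 0.80 without 15C4 1.

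Hypoxia response genes fell, with 15 of 20 fitted below 0 and a median log2 difference of -0.63 (camera adjusted p = 0.0457; adjusted p = 0.757 with an estimated correlation). Their summed CPM was 6116 ± 2031 in 15C4 and 10142 ± 2151 in IgG (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest possible). Ero1l, an endoplasmic reticulum oxidase, was at 538 ± 371 against 1767 ± 633 CPM, and P4ha2, a collagen prolyl hydroxylase, at 48.5 ± 13.7 against 107 ± 41.9 CPM. The call was lost without 15C4 1 (median -0.77, adjusted p = 0.177), 15C4 2 (-0.71, 0.0860), 15C4 3 (-0.26, 0.237), IgG 2 (-0.53, 0.229) or IgG 3 (-0.64, 0.0917).

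**Figure D3:**
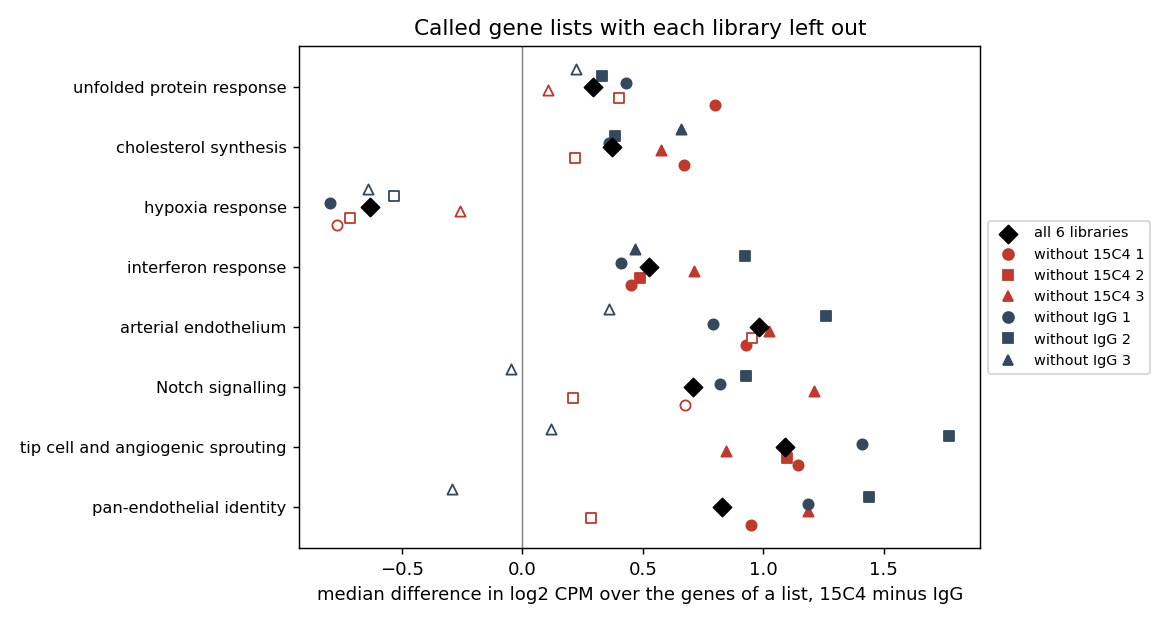
Median difference in log2 CPM, 15C4 minus IgG, over the genes of the 8 lists that passed, with all libraries (black diamonds) and with each library left out (red, a 15C4 library; blue, an IgG library; open symbols, adjusted p of 0.05 or more). Without IgG 3 the pan-endothelial median is -0.29 against 0.83 with all libraries.

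Other lists did not pass. Cell cycle genes had 24 of 34 members fitted below 0 (median -0.40, adjusted p = 0.0522). Aurkb was the 1 member that passed adjusted over the list alone (edgeR quasi-likelihood test, adjusted p = 0.0322), and 0 members passed over all genes. Nusap1 was at 4.77 ± 2.75 against 59.5 ± 55.5 CPM, Tk1 at 6.37 ± 4.44 against 34.4 ± 15.8 CPM and Mcm6 at 33.0 ± 11.4 against 85.9 ± 8.90 CPM. The summed cell cycle CPM was highest in IgG 1, at 4787 against 1432 to 3183 in the others, the library with the most T and NK cell transcripts. No member of any other list passed adjusted over the list alone. Glycolysis genes had 15 of 17 members below 0 (median -0.58, adjusted p = 0.0865), with Gpi1 at 457 ± 61.9 against 840 ± 281 CPM and Pfkp at 198 ± 70.6 against 357 ± 34.0 CPM. Of the TGF-beta and BMP pathway components, 6 were above and 10 below 0 (median -0.11, adjusted p = 0.945), with Tgfb3, a TGF-beta ligand, at 2 counts in 15C4 and 72 in IgG, a ratio of 43.9 (95% counting interval 11.7 to 370), and Smad4 at 70.0 ± 33.5 against 144 ± 43.1 CPM. Of the genes responsive to this pathway, 11 of 14 were above 0 (median 0.51, adjusted p = 0.137), among them Id2, while Cdkn1a was at 59.1 ± 8.85 against 148 ± 64.1 CPM.

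The remaining endothelial lists were basement membrane (median 0.49, adjusted p = 0.0522), junction and barrier (0.49, 0.0800), leukocyte adhesion (0.56, 0.220), capillary (0.27, 0.407), flow responsive (0.08, 0.546) and venous (-0.32, 0.918). Among processes, oxidative phosphorylation had a median of 0.02 (adjusted p = 0.167), MHC class I presentation -0.13 (0.780), MHC class II presentation -2.34 (0.113), NF-kappaB response -0.48 (0.837), endothelial to mesenchymal transition -0.48 (0.945), lipid handling -0.20 (0.945) and p53 and apoptosis -0.32 (0.463). Of the RNA quality lists, dissociation stress had a median of 0.15 (0.400), ribosomal proteins -0.10 (0.945) and nuclear retained RNAs 0.24 (0.315). The melanocyte (0.19, 0.137), pericyte (0.98, 0.240), macrophage (-1.95, 0.400), T and NK cell (-2.39, 0.396) and fibroblast lists (-1.21, 0.490) did not pass either. Camera sets a list against all other tested genes, whose mean difference was -0.37. Its direction was higher for MHC class I, ribosomal protein, lipid and endothelial to mesenchymal genes, although their medians were below 0. The mean differed in sign from the median for the capillary (-0.03) and dissociation stress lists (-0.18). The edgeR fits went the other way from the log2 CPM medians for MHC class II (5 of 7 members above 0, median 0.20), endothelial to mesenchymal transition (7 of 11, 0.22) and lipid handling (7 of 13, 0.10).

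Some lists passed the camera test with a preset correlation under another filter or when 1 library was left out. None of these calls held in the same setting with an estimated correlation, where the smallest adjusted p of any list was 0.779 with the stricter filter and at least 0.698 with 1 library left out. With genes of a mean count of at least 50, cell cycle (adjusted p = 0.0250) and glycolysis genes (0.0298) passed as lower. MHC class II presentation passed as lower without 15C4 2 (median -3.77, adjusted p = 0.0165). Cell cycle genes passed as lower without 15C4 3 (-0.36, 0.00912), IgG 2 (-0.55, 0.00946) or IgG 3 (-0.67, 0.0125), glycolysis without IgG 1 (-0.67, 0.0264) and T and NK cell genes without IgG 3 (-3.88, 0.00229). Basement membrane genes passed as higher without 15C4 3 (0.69, 0.0248), IgG 1 (0.73, 0.0224) or IgG 2 (0.81, 0.00262), and junction genes without 15C4 3 (0.82, 0.0495) or IgG 2 (0.78, 0.00278). Leukocyte adhesion genes did so without IgG 1 (0.70, 0.0267) or IgG 2 (0.81, 0.0228), and oxidative phosphorylation genes without 15C4 1 (0.31, 0.00718) or IgG 3 (0.30, 0.00238). TGF-beta and BMP responsive genes passed without IgG 1 (0.93, 0.0368) and dissociation stress genes without 15C4 3 (0.73, 0.00960).

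In these lists, the members with the smallest unadjusted p, none of which passed, had the following edgeR log2 fold changes. Lama4, a laminin chain of the vascular basement membrane, had 0.56 (SE 0.32) and Nid1 0.99 (SE 0.70). Among junction genes, Jam3 had -1.08 (SE 0.62) and Ctnnb1, which encodes beta-catenin, 0.48 (SE 0.30). Capillary Rgcc had 1.02 (SE 0.82) and Cd300lg 1.18 (SE 1.06), venous Vwf -1.03 (SE 1.14) and Selp -2.21 (SE 2.47), and flow responsive Klf2 0.78 (SE 0.79) and Hmox1 -0.61 (SE 0.78). Ackr1, a chemokine-binding receptor of venules, had 1.94 (SE 2.52). Among the processes, Uqcrc1 had 0.78 (SE 0.44) and Ndufs1 0.52 (SE 0.36), Tapbp 0.84 (SE 0.53) and Tap2 1.01 (SE 0.81), H2-DMb1 -2.14 (SE 1.19) and Ctss 1.66 (SE 2.20). Acta2, the smooth muscle actin gene, had 4.11 (SE 2.20) and Cdh2 -1.03 (SE 0.71), Nfkbia -0.84 (SE 0.83) and Tnfaip2 0.30 (SE 0.51), Acadl -0.51 (SE 0.32) and Cpt1a -0.65 (SE 0.60), and Eda2r -3.39 (SE 1.56). Of the quality lists, Klf6 had 0.75 (SE 0.36), Nr4a1 0.69 (SE 0.54), Rpl8 -0.44 (SE 0.33), Rps6 0.45 (SE 0.35), Xist 0.99 (SE 0.83) and Kcnq1ot1 0.36 (SE 0.45). Among markers of other cells, Gzma had -5.90 (SE 1.92), Nkg7 -5.29 (SE 2.03) and Ptprc -5.65 (SE 2.17), all with their highest CPM in IgG 1. Fcer1g had -1.11 (SE 1.70), Trpm1 0.59 (SE 0.29), Oca2 0.75 (SE 0.44), Zbtb46 -2.14 (SE 1.34), Lum 2.89 (SE 2.74), Mmp2 -0.66 (SE 1.49), Kcnj8 -1.43 (SE 1.30), Flt4 -0.83 (SE 0.98), Pdpn 0.56 (SE 1.40) and Ckm -2.80 (SE 2.09).

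The authors' deposited table lists 507 genes at an adjusted p under 0.05, 383 higher in IgG and 124 higher in 15C4. Of these, 57 (11.2%) had over 90% of their normalised counts in 1 library, 30 of them in IgG 2. Lyve1 (log2 26.66 for IgG over 15C4, adjusted p = 4.15e-20), Nts (27.46, 3.03e-18) and Reln (24.39, 4.03e-11) in the authors' deposited table were among these 30. The share of such genes among all with an adjusted p in that table was 8.47%, and 338 of the 507 genes did not overlap between the groups. Aurkb (5.63, adjusted p = 2.1e-09) and Ifih1 (-1.71, adjusted p = 0.00214) were also called in the authors' deposited table. Of the 278 called genes tested with edgeR, 187 had an unadjusted p under 0.05.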

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

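The endothelial covariate, the fit without 15C4 3 and IgG 3, DESeq2 without a prior filter, and an estimated correlation combined with another setting were chosen after seeing the data. The edgeR count of 0 genes was also found with other normalisations, the stricter filter, robust shrinkage, limma-voom, an adjusted p under 0.1, a 1.5-fold threshold, the endothelial covariate, each library left out and both of 15C4 3 and IgG 3 left out. Without the low-count filter, 1 gene was called, lower in 15C4: 3830403N18Rik, named after its values were seen. DESeq2 called 26 genes (3 higher, 23 lower), 65 without a prior filter (18 higher, 47 lower) and 121 with its outlier cutoff also off (44 higher, 77 lower). The deposited table shared 26, 60 and 90 of these, and the cause of its 507 calls was not tested. Of the 20 named genes, 13 passed with DESeq2 and 0 reversed in direction under the alternatives that tested them. These genes were chosen for the smallest p in the same counts, so neither number is independent support. The count of 8 lists became 0 with an estimated correlation and 0 with fry for a shared direction. It was also 0 with the endothelial covariate and an estimated correlation. It was 5 without 15C4 3 and IgG 3, of which 2 were among the 8, interferon response and cholesterol synthesis. It was 10 with a mean count of at least 50, all 8 among them. With the endothelial covariate at the preset correlation it was 9, 6 of them among the 8. There the Notch call was lost (camera adjusted p = 0.158), and venous, cell cycle and oxidative phosphorylation genes gained one. The pan-endothelial call was lost too (camera adjusted p = 0.324), but this was fixed in advance, since the covariate is the mean of that same list. With each library left out the count of lists ranged from 3 (without 15C4 2) to 12 (without IgG 1). With an estimated correlation it was 0 with the stricter filter, with the replicate block, without 15C4 3 and IgG 3, and with each library left out (smallest adjusted p = 0.698 with an estimated correlation). The pan-endothelial median reversed to -0.29 without IgG 3 and was at most 1.44, without IgG 2.

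Same-numbered libraries deviated from their group means with correlations of -0.04, 0.06 and 0.10, against -0.104 to 0.0678 for pairs of unlike number. These values show no clear pairing by number. With 3 libraries per group they cannot exclude one, and the labels do not say whether equal numbers share an animal or day. The replicate block gave 0 genes and 9 lists, 7 of them among the 8, and ended the hypoxia call (adjusted p = 0.0961). The counts limit genes near 0: 3 counts equal 0.153 to 0.580 CPM, depending on the library.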

Other observations

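The tests of the IgG 3 library, of tumour content, of the tip cell ratio, of depth and of drop-out were chosen after their results had been seen; the counts over other splits were set beforehand.

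Venous genes had a median log2 difference of -1.81 without IgG 3 (adjusted p = 0.0903), with 7 of 9 members fitted below 0 when all libraries were used, and passed as lower with the endothelial covariate, which was added after seeing the data (median -1.36, adjusted p = 0.0393; the smallest of any list was 0.684 with an estimated correlation). The summed CPM of venous genes overlapped, at 394, 434 and 125 in 15C4 and 316, 754 and 154 in IgG (two-sided exact permutation p = 0.9). It was highest in IgG 2, the library with the most transcripts of lymphatic endothelium. The components of the TGF-beta and BMP pathway had an unadjusted fry p of 0.000982 for change in either direction. It was the smallest such p of the 33 lists and was not adjusted over them. This test does not set the components against other genes.

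Of 12 endothelial lists, 4 passed as higher in 15C4 with a preset correlation, and none with an estimated one (adjusted p = 0.757 with an estimated correlation). The low endothelial content of IgG 3 may account for this, since the pan-endothelial median went from 0.83 to -0.29 without that library and 0 of the 4 endothelial lists kept their call. A smaller share of tumour cells in 15C4 cannot be told apart from it: the melanocyte list had a median of 0.19, but despite the endothelial sort melanocyte transcripts exceed endothelial ones at least 6.97-fold, so a small fall would not show. A treatment effect on tip cell genes relative to other endothelial genes also stays open. The ratio of tip cell to pan-endothelial CPM was 2.41, 1.39 and 2.92 in 15C4 and 1.44, 1.93 and 2.87 in IgG (exact permutation p = 0.9, two-sided), while with the endothelial covariate the tip cell median was 0.57 instead of 1.09, with an adjusted p of 0.00793 at the preset correlation and adjusted p = 0.684 with an estimated correlation.

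A set of 18 genes lay under 1 CPM in all 15C4 libraries and at 5 CPM or more in all IgG libraries, among them Rab39b, Kcnn4, Gnai1 and Aurkb, against 1 gene in the mirrored pattern. The totals alone do not settle whether lower depth of the 15C4 libraries is the cause. Their mean was 1.30 times that of IgG but 0.838 times without 15C4 2, while the shallowest library was IgG 1. In the 15C4 libraries 3 counts equal 0.153 to 0.469 CPM, well under the 5 CPM reached in every IgG library, IgG 1 included. This argues against lower read depth as the cause for these 18 genes. Drop-out of genes from single libraries may give this number: 32 genes were missing in the same way from 15C4 1, 15C4 3 and IgG 3, and each library's own rate gives 21.7 genes for the 15C4 libraries (95% range 14 to 30). The 15C4 libraries had 63, 31 and 560 genes missing from 1 library alone and the IgG libraries 0, 12 and 51, and the rates were estimated with the 18 included, so a treatment effect on some of the 18 stays open and was not tested.

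The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 0 genes and the highest other also 0, so 10 of 10 gave as many (288 genes had an unadjusted p under 0.05 by edgeR, where limma-voom called 0 and DESeq2 26). For lists, 5 of 10 splits gave as many as the real 8, and the highest other gave 14, with 15C4 1, 15C4 2 and IgG 2 on one side.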
